A study of Mus musculus with 89 samples.

How the data were processed

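Lung RNA from male mice was hybridized to 89 Affymetrix HT Mouse430PM arrays after NuGEN amplification, in 18 groups of 2 to 6 arrays (3 strains and 6 exposures). The deposited log2 signals of 45141 probe sets were normalized by the authors, with software not given in the sources used here. The values ran from 1.86 to 13.5, and every array had the same median of 4.90 and the same quartiles. Nothing beyond the replicate numbers in the labels says that the arrays are separate animals, and their number per group limits the precision.

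Of the probe sets, 28898 mapped to 1 gene symbol, 551 to several and 15692 to none here, and 104 were controls. They covered 17097 genes, 7180 of them with over 1 probe set. Each gene was represented by the probe set with the highest mean over the 89 arrays. A gene was tested if it was above the 40th percentile of all values (log2 4.45) on at least 4 arrays, which left 15065 genes. This filter was chosen before the data were examined, as were the comparisons, the 32 gene lists, the rule for named genes and the alternatives given first in the closing section.

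Group means were fitted to all 89 arrays with limma 3.58.1 in R 4.3.3, and 27 comparisons were taken as contrasts. They were ozone against air, Af 24 h and Af 168 h with air against air, Af 96 h with ozone against ozone alone, and ozone against air at Af 168 h in each strain, the strains against each other in air, and differences between these responses. The moderated test of limma was two-sided, and p was adjusted by Benjamini and Hochberg over the genes of a comparison, with calls at an adjusted p under 0.05. The 32 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Beside each count over all genes stands the count adjusted over the list alone. Changes are given as log2 change ± SE from the fit and group levels as mean ± SD.

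The genes named were chosen by a fixed rule. For each comparison it takes the 8 largest rises and the 8 largest falls among called genes. For each list called by camera it adds the 3 called members with the largest change, and Sftpd is taken in every comparison. Gene models and accession-like names are passed over. Genes outside the rule are marked as chosen after their values were seen.

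The strain index places an array between the C57BL/6 air mean (-1) and the BALB/c air mean (1) by the median over 40 genes, 15 of them higher and 25 lower in BALB/c. A wild-type label was doubted with Sftpd under 9, and an SP-D-/- label with Sftpd above 8. A BALB/c label was doubted with an index under 0, and any other label with an index above 0. This gave 5 arrays. The spike level of an array is the mean of 10 hybridization control probe sets. Groups were compared in spike level by an exact permutation test over 15 pairs of groups, and correlations across arrays were tested with 100000 permutations, as were strain labels within exposures for 9 air genes. The fit without the 5 arrays and with the spike level as a covariate (84 arrays) was added after seeing the data, as were each of these changes alone, the same fit with a replicate block and the same fit with the actin difference. The actin difference is the log2 signal of the 3' minus that of the 5' beta-actin control probe set. It was compared between the same 15 pairs of groups by the same test.

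The alternatives chosen first were cyclic loess between arrays, the mean of all probe sets of a gene (14622 genes), no filter, a fit of only the groups of the comparison, the replicate number as a block and leaving out each array. The replicate numbers were checked as pairs by correlating residuals of arrays with the same number. All pairs exceeded 0.1 only for ozone against air at Af 168 h in C57BL/6 (4 of 4, mean 0.337, against -0.06 for different numbers). There 2 of 4 arrays correlated best with their own number, so pairing, which the labels do not explain, stays open. The planned fit has no block, and the block is among the alternatives.

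The fit was tested on simulated data with the real means and residual SDs of 15065 genes, of which 100 were changed at each of 2 sizes. Correlation between genes was not simulated, so false calls under it were not tested. For ozone against air in C57BL/6 it recovered 37% at a log2 change of 1 and 92% at 2, with 4 false calls, and in BALB/c 10% and 62%, with 3. For Af 24 h it recovered 33% and 88% in C57BL/6, with 3, and 31% and 92% in SP-D-/-, with 7. For the difference between these it recovered 5% and 58%, with 2. A list shifted by 0.7 ranked first in each, with adjusted p of 8.1e-05, 0.135, 1.4e-08, 0.00189 and 0.00207 in that order. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. BALB/c and C57BL/6 responses were compared only for ozone and Af 24 h, as planned.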

Results

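RNA from the left lung lobe of male mice was measured on 89 Affymetrix arrays in 18 groups. The 3 strains were C57BL/6, BALB/c and SP-D-/-, a strain with a disrupted Sftpd gene. Sftpd encodes surfactant protein D, a collectin of the airspace that binds microbes and allergens. Mice breathed air or ozone (3 ppm) for 2 h and were sampled 12 h later. Allergen groups were first sensitized to the mould Aspergillus fumigatus (Af) on days 0 and 7 and challenged through the nose on day 13. They were sampled 24 h after challenge with air, 96 h after challenge with ozone, and 168 h after challenge with air or with ozone. In the order air, ozone, Af 24 h, Af 96 h with ozone, Af 168 h with air and Af 168 h with ozone, C57BL/6 had 6, 6, 4, 5, 4 and 6 arrays. SP-D-/- had 5, 4, 6, 6, 5 and 4, and BALB/c had 5, 2, 5, 6, 6 and 4. No Af 24 h group with ozone and no Af 96 h group with air was present, so the Af 96 h groups were compared with ozone alone. The number of arrays limits the precision, most of all in BALB/c given ozone alone. The comparisons asked how lung expression responded to ozone, to the allergen and to both, and how it differed without surfactant protein D.

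Sftpd was lower in SP-D-/- than in C57BL/6 lungs under all 6 exposures. In air the difference was -3.84 ± 0.53 (log2 ± SE, adjusted p = 1.94e-06), from 10.16 ± 0.27 (mean log2 ± SD) in C57BL/6 to 6.32 ± 0.34 in SP-D-/-, a 14.3-fold lower signal. It was -4.64 ± 0.56 with ozone (adjusted p = 2.67e-08) and -3.54 ± 0.56 at Af 24 h (adjusted p = 9.19e-05). At Af 168 h it was -3.44 ± 0.58 with air (adjusted p = 0.000489) and -4.08 ± 0.56 with ozone (adjusted p = 4.35e-06). The smallest difference was -2.90 ± 0.53 at Af 96 h with ozone (adjusted p = 0.000554), where the SD in SP-D-/- was 1.56. Without the arrays labelled C57BL/6 and SP-D-/- Af 96 h replicate 1 the difference was -3.47. The array holds 1 probe set for Sftpd, and the part of the gene that was deleted is not given, so a probe set outside that part would check nothing about the knockout.

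**Figure D1:**
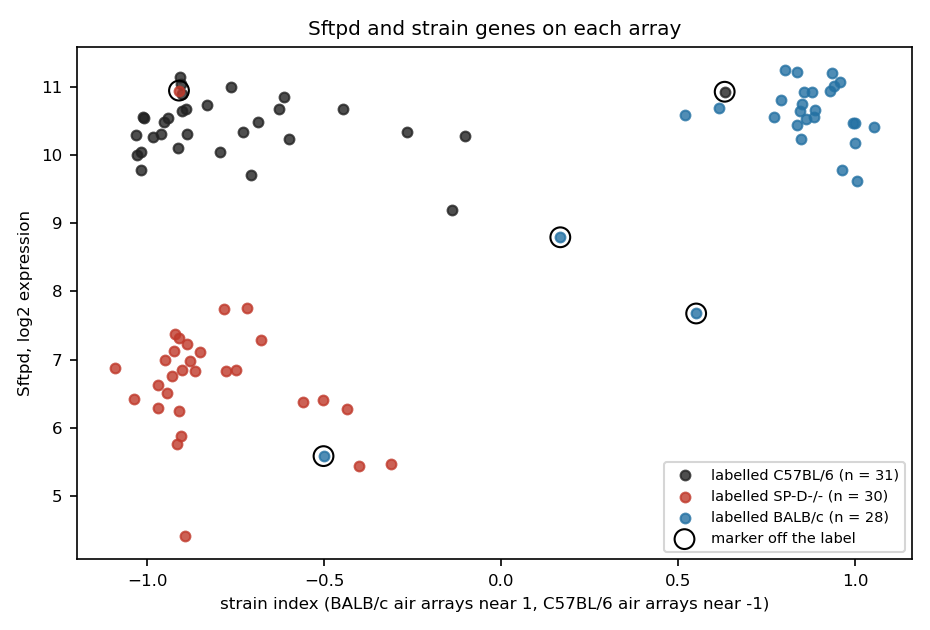
Sftpd level (log2, vertical axis) against a strain index from 40 genes that differ between BALB/c and C57BL/6 (horizontal axis), 1 point per array, coloured by the strain on the label. Of the 89 arrays, 5 lie away from the others of their label, among them 1 labelled SP-D-/- with Sftpd at 10.94.

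Strain markers of 5 arrays did not match their labels. The strain index is the median position of an array over 40 genes that differ between BALB/c and C57BL/6 in air, above 0 on the BALB/c side and under 0 on the C57BL/6 side. The array labelled BALB/c Af 168 h with ozone replicate 6 had Sftpd at 5.59 and a strain index of -0.50. The array labelled C57BL/6 Af 96 h with ozone replicate 1 had an index of 0.63, on the BALB/c side, with Sftpd at 10.93. The array labelled SP-D-/- Af 96 h with ozone replicate 1 had Sftpd at 10.94 and an index of -0.91. The arrays labelled BALB/c Af 24 h replicates 4 and 5 had indices of 0.17 and 0.55, on the BALB/c side, with Sftpd at 8.79 and 7.68, under the level of 9 taken for wild-type labels.

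Arrays also differed in signal. The mean of 10 hybridization control probe sets, for RNA added to each array mix, followed the first principal component of the 5000 most variable genes, which held 41.8% of their variance. Across the 89 arrays Pearson's r was 0.898 and Spearman's rho 0.944 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Within groups r was 0.895 and rho 0.907 (permutation p = 1e-05 for each), and r was 0.907 without the 2 arrays farthest from the median. Over the 4 relations tested the adjusted p of each of these was 1.33e-05. This spike level was 10.90 ± 0.45 (mean ± SD, n = 5) at Af 96 h with ozone and 8.59 ± 1.14 (n = 6) with ozone alone in C57BL/6 (exact permutation p = 0.013, two-sided, and 0.195 adjusted over 15 tests). Counts of genes are therefore given for all arrays and for a fit without the 5 arrays and with the spike level as a covariate, called the spike-adjusted fit. It was added after seeing the data.

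The actin difference, the 3' minus the 5' beta-actin log2 signal, is a sign of RNA quality. Within groups it followed the spike level with r = 0.341 and rho = 0.337 (permutation p = 0.00095 and 0.00137, and the same adjusted over the 4 relations). It was 1.59 ± 0.16 in C57BL/6 air, 1.88 ± 0.17 in SP-D-/- air and 1.71 ± 0.36 in BALB/c air (mean ± SD, n = 6, 5 and 5), and is given below with exact two-sided permutation tests over 15 pairs of groups. The actin fit, also added after seeing the data, is the spike-adjusted fit with this difference as a further covariate. Where a group mean lay under the filter level of 4.45, near background, the size of a change is approximate. This holds for Hoatz, Cxcl2, Foxj1, Cyp2e1, Serpina1c, Adipoq, Slc26a4 in BALB/c, Acta1, Cd93, Ccl8 in BALB/c at 96 h, the Igkv14 segment, Loxl2, Fgg, Fga, Klra8 and Ndnf, and where stated below. After challenge Retnla ran from 10.99 to 13.32, against a highest value of 13.5 on any array, so its rises there may be too low.

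**Figure D2:**
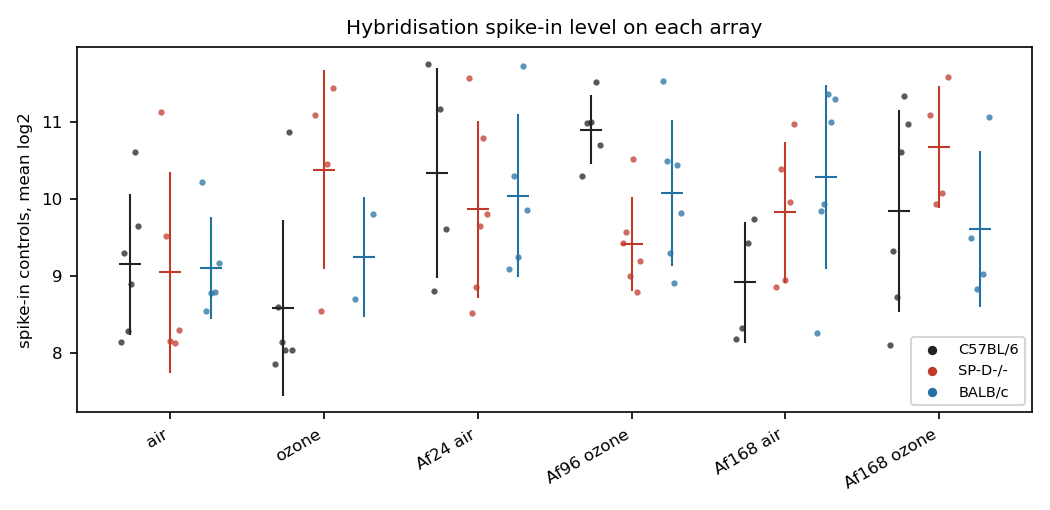
Mean level of the hybridization control probe sets (log2, vertical axis) for each array by group, with the mean and SD of each group. In C57BL/6 the mean was 10.90 at Af 96 h with ozone and 8.59 with ozone alone.

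Ozone alone raised a small set of genes in C57BL/6 lungs. Saa3, an acute-phase serum amyloid, rose by 3.08 ± 0.50 (log2 change ± SE, adjusted p = 0.000295), from 4.98 ± 0.79 (mean log2 ± SD) in air to 8.06 ± 0.89 (n = 6 and 6). Timp1, an inhibitor of matrix metalloproteinases, rose by 2.99 ± 0.57 (adjusted p = 0.00625). Retnla, a product of alternatively activated macrophages, rose by 1.71 ± 0.28 (adjusted p = 0.000295), and Krt7, an epithelial keratin, by 1.30 ± 0.27 (adjusted p = 0.0306). Among 11 acute-phase and metallothionein genes 2 rose and none fell (7 rose adjusted over the list alone), and the list rose as a set (camera adjusted p = 2.62e-32, and 5.42e-07 with an estimated correlation). NRF2 antioxidant genes, which detoxify oxidants, rose as a set with a median of 0.37 (adjusted p = 1.08e-07, and 0.0334 with an estimated correlation), although none of 19 members passed, also adjusted over the list alone. Inflammatory chemokines and cytokines rose as a set (adjusted p = 7.98e-06, and 0.0273 with an estimated correlation), as did glucocorticoid-responsive genes (adjusted p = 2.06e-06, and 0.0498), with no member of 15 and of 12 passing. Adjusted over the list alone 0 of the 15 and 3 of the 12 rose. In all, 4 genes rose and 0 fell (limma), with 187 at an unadjusted p under 0.05. Krt7 lost its call without any of air replicates 2 to 6 or ozone replicates 1, 3, 4 and 6 (adjusted p up to 0.23).

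In BALB/c lungs Retnla rose with ozone by 3.54 ± 0.41 (adjusted p = 7.36e-09), from 8.21 ± 0.63 to 11.75 ± 0.09 (n = 5 and 2). Saa3 rose by 4.43 ± 0.72 (adjusted p = 0.000276), but not without ozone replicate 1 (adjusted p = 0.257), which left a count of 1. These 2 genes were all that passed, with 157 at an unadjusted p under 0.05. The acute-phase list rose as a set, with 1 of 11 members passing (1 adjusted over the list alone, camera adjusted p = 1.74e-16, and 0.000862 with an estimated correlation). Skeletal muscle genes fell as a set, with a median of -3.58 over 8 genes (adjusted p = 1.32e-25, and 0.00146 with an estimated correlation). None of the 8 passed over all genes, and 8 of 8 fell adjusted over the list alone. Their mean level in BALB/c air arrays ran from 4.81 to 10.67.

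In SP-D-/- lungs 1 gene rose and 14 fell with ozone, and these calls rested on single arrays. Tspan1, a tetraspanin of airway epithelium, fell by 2.16 ± 0.42 on the log2 scale (adjusted p = 0.0101), from 8.70 ± 0.49 to 6.53 ± 0.58 (n = 5 and 4), and was the 1 gene called in the spike-adjusted fit, whose count was 17, 19 and 7 without air replicates 2, 6 and 5, and 33, 6 and 0 without ozone replicates 3, 4 and 5. The actin difference was 2.75 ± 0.39 with ozone against 1.88 ± 0.17 in air (exact p = 0.0159, and 0.034 adjusted), and the actin fit called 0 genes (limma, 1128 at an unadjusted p under 0.05), with Tspan1 at -2.06 (adjusted p = 0.0749). Without ozone replicate 5 its adjusted p was 0.117. The count of 15 changed by over 1.5 times without any of the 9 arrays. It was 1 without ozone replicate 2 or 5, 454 without ozone replicate 3, 28 without ozone replicate 4, and 8, 46, 28, 27 and 7 without air replicates 3, 2, 6, 5 and 4.

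Saa3 had 1.47 and Retnla 0.49 in SP-D-/- and neither passed (adjusted p = 0.208 and 0.41), but the difference from C57BL/6 was not called for any gene (limma, 0 genes, 1157 at an unadjusted p under 0.05). In SP-D-/- the acute-phase list, higher in air, was lower in that test (median -1.30, camera adjusted p = 0.00193, and 0.899 with an estimated correlation), with 0 of 11 passing and 0 adjusted over the list alone. The count of 0 was 10, 8 and 7 without SP-D-/- air replicates 2, 6 and 5, 3 without C57BL/6 ozone replicate 5 and 1 without SP-D-/- ozone replicate 3, all of them genes lower in SP-D-/-. The same test between BALB/c and C57BL/6 called 0 genes, with 131 at an unadjusted p under 0.05. Across 15065 genes the ozone changes of C57BL/6 and SP-D-/- correlated with r = -0.025 (rho = -0.014) and those of SP-D-/- and BALB/c with r = 0.306 (rho = 0.312). For C57BL/6 and BALB/c r was 0.027 (rho = 0.011). Genes are not independent replicates, and the first r was 0.208 in the spike-adjusted fit and ran from -0.343 to 0.224 when 1 array was left out.

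**Figure D3:**
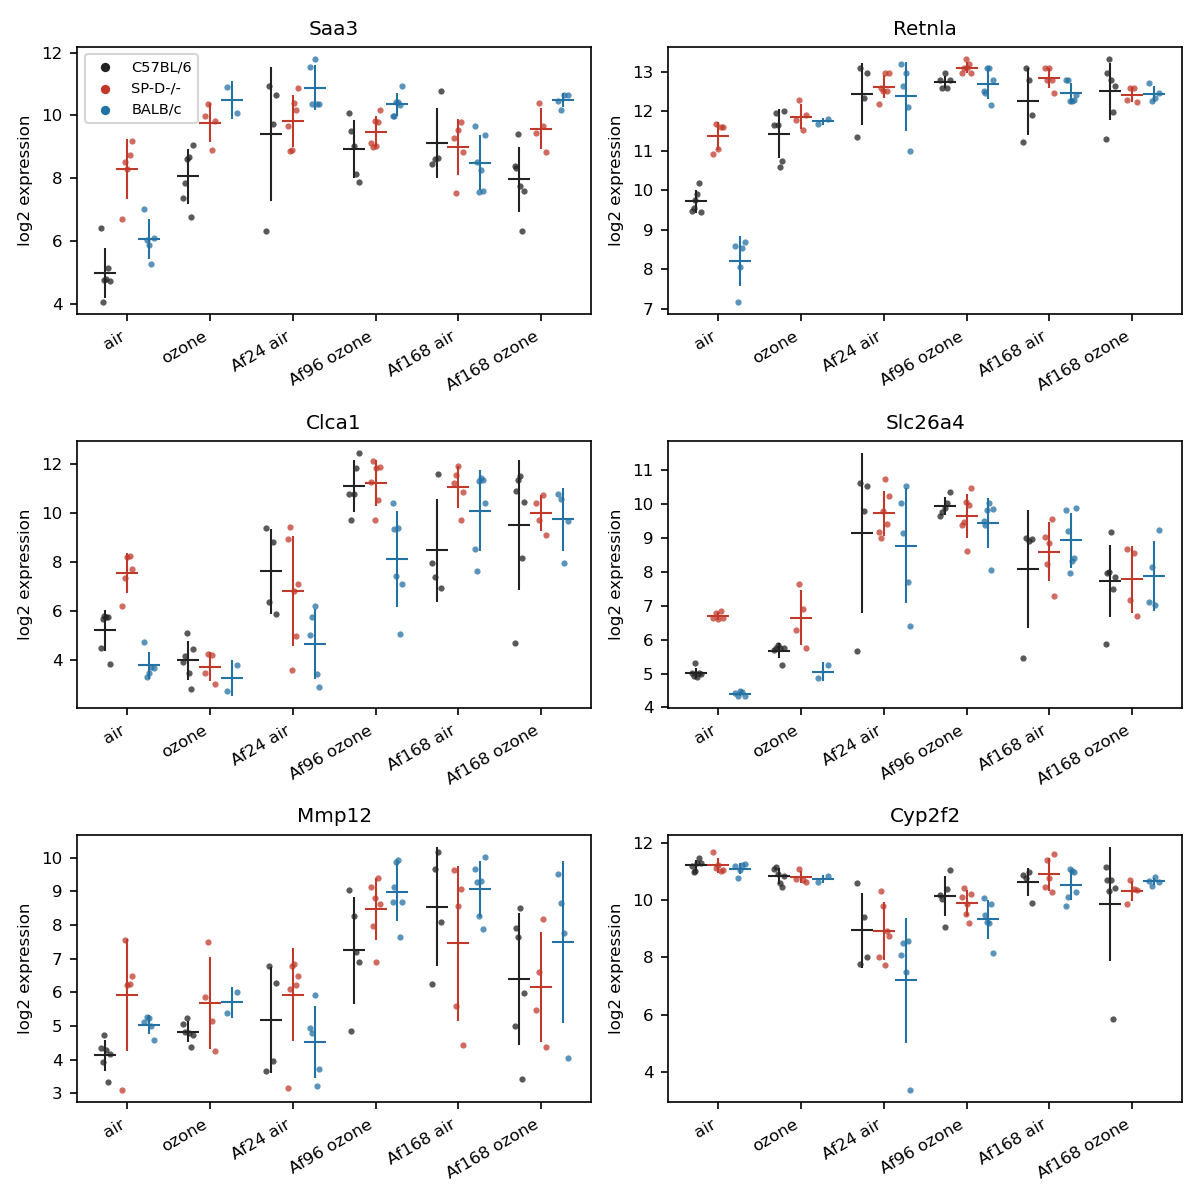
Levels (log2, vertical axis) of 6 genes in each of the 18 groups, 1 point per array with the mean and SD of the group. In C57BL/6 Saa3 went from 4.98 in air to 8.06 with ozone and 9.40 at Af 24 h.

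At 24 h after allergen challenge, Saa3 and type 2 genes rose in C57BL/6 lungs. Saa3 rose by 4.42 ± 0.56 (log2 change ± SE, adjusted p = 7.32e-08) and Slc26a4, the anion exchanger pendrin of airway epithelium, by 4.13 ± 0.60 (adjusted p = 3.78e-06), from 5.02 ± 0.15 to 9.15 ± 2.35 (mean log2 ± SD, n = 6 and 4). The array labelled replicate 1 had Saa3 at 6.31 and Slc26a4 at 5.67, where the others ran from 9.71 to 10.93 and from 9.78 to 10.63, and without it they rose by 5.45 and 5.29. Retnla rose by 2.71, Arg1, an enzyme of alternatively activated macrophages, by 2.47, and Ccl24, an eosinophil attractant, by 2.17. Type 2 genes rose as a set, 7 of 18 up and 0 down (10 up adjusted over the list alone, camera adjusted p = 2.85e-06, and 0.211 with an estimated correlation). Inflammatory chemokines and cytokines rose as a set, 8 of 15 up and 0 down (8 up and 1 down adjusted over the list alone), among them the neutrophil attractant Cxcl2, by 1.82 ± 0.43 (set adjusted p = 0.000384, and 0.211 with an estimated correlation).

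Airway epithelial genes fell at the same time in C57BL/6. Of 14 club and secretory cell genes 7 fell and 0 rose (10 fell adjusted over the list alone), among them Scgb3a2, a secretoglobin, by 2.39 ± 0.54, and Cyp2a5, a xenobiotic oxidase, by 2.48 ± 0.68. Of 12 ciliated cell genes 9 fell and 0 rose (10 fell adjusted over the list alone), among them Lrrc23, a radial spoke gene, by 1.93 ± 0.39. Both lists fell as a set (camera adjusted p = 3.51e-06 each, and 0.307 each with an estimated correlation). Hoatz, a gene of motile cilia, fell by 4.10 ± 0.61 and Pon1, a paraoxonase, by 3.76 ± 0.60. Cyp2f2, the club cell cytochrome, chosen after its values were seen, was 10.60 on replicate 1 and ran from 7.76 to 9.41 on the others. The actin difference was 2.84 ± 0.54 at Af 24 h (exact p = 0.00952 against air, and 0.0238 adjusted). The actin fit called 256 genes that rose and 256 that fell, 488 shared with the spike-adjusted fit, with Saa3 at 4.70 and Slc26a4 at 4.08. In it 3 club and 3 ciliated genes fell (9 and 9 adjusted over the list alone, camera adjusted p = 5.38e-07 and 2.07e-06, and 0.131 each with an estimated correlation), and 7 type 2 genes rose (13 adjusted over the list alone, adjusted p = 2.69e-14, and 0.00169 with an estimated correlation). In all, 964 genes rose and 1473 fell, and 925 rose and 1002 fell in the spike-adjusted fit, with 1570 shared in sign. The count of 2437 was 944 without Af 24 h replicate 1, 4076 without replicate 3 and 1516 without replicate 4.

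In SP-D-/- lungs the airway genes also fell at 24 h. Of 14 club and secretory genes 9 fell and 0 rose (14 fell adjusted over the list alone), and of 12 ciliated genes 11 fell and 0 rose (12 fell adjusted over the list alone). Both sets fell (adjusted p = 1.64e-16 and 5.54e-16, and 0.0103 each with an estimated correlation). Scgb3a1, a secretoglobin, fell by 2.83 ± 0.59 (adjusted p = 0.00123), Gabrp, a GABA receptor subunit of secretory epithelium, by 2.64 ± 0.37 (adjusted p = 2.92e-06) and Foxj1, the regulator of motile ciliogenesis, by 2.02 ± 0.44 (adjusted p = 0.002), from 6.35 ± 0.47 to 4.33 ± 0.58 (n = 5 and 6). Sprr1a, a cornified envelope gene of stressed epithelium, rose by 3.74 ± 0.49 (adjusted p = 5.42e-07) and Slc26a4 by 3.02 ± 0.57 (adjusted p = 0.000399). Inflammatory chemokines rose as a set, 5 of 15 up (7 adjusted over the list alone), among them Ccl2, a monocyte attractant, by 1.40 ± 0.34 (set adjusted p = 2.43e-06, and 0.0103 with an estimated correlation). Type 2 genes rose as a set, 9 of 18 up (10 adjusted over the list alone, set adjusted p = 3.46e-08, and 0.0505 with an estimated correlation). At Af 24 h the actin difference was 2.54 ± 0.29 (exact p = 0.00433 against air, and 0.0238 adjusted). The actin fit called 295 genes that rose and 336 that fell, 610 shared with the spike-adjusted fit. In all, 241 genes rose and 468 fell, and 446 rose and 491 fell in the spike-adjusted fit, with 660 shared in sign. The count of 709 was 462, 470 and 444 without air replicates 3, 5 and 4, and 435 without Af 24 h replicate 5. The spike-adjusted count of 937 was 606 without air replicate 3.

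In BALB/c lungs all 14 club and secretory genes fell at 24 h, also adjusted over the list alone (camera adjusted p = 2.28e-16, and 0.0187 with an estimated correlation). Cyp2f2 fell by 3.90 ± 0.57 (adjusted p = 2.21e-06) and Scgb3a2 by 3.63 ± 0.53 (adjusted p = 2.21e-06), from 11.37 ± 0.20 to 7.74 ± 1.96 (n = 5 and 5). The array labelled replicate 5 had Cyp2f2 at 3.36, where the others ran from 7.49 to 8.57, and its club and secretory genes differed by -2.31 from replicates 1 to 3. In the spike-adjusted fit, which leaves out the arrays labelled replicates 4 and 5, Cyp2f2 had -3.07, and 9 of the 14 genes fell (12 adjusted over the list alone, set adjusted p = 3.28e-14, and 0.0137 with an estimated correlation). Retnla rose by 4.17 ± 0.31 (adjusted p = 8.39e-18), Saa3 by 4.81 ± 0.55 (adjusted p = 2.27e-09) and Ccl8, a chemokine for eosinophils and monocytes, by 3.35 ± 0.67 (adjusted p = 0.00039). Inflammatory chemokines rose as a set, 7 of 15 up (7 adjusted over the list alone, set adjusted p = 1.29e-05, and 0.0217 with an estimated correlation). Cell cycle genes rose as a set, 10 of 27 up (17 adjusted over the list alone), among them Mki67, a proliferation marker, by 1.82 ± 0.34 (set adjusted p = 2.37e-10, and 0.0187 with an estimated correlation). These genes were 1.64 higher on the array labelled replicate 5 than on replicates 1 to 3, and in the spike-adjusted fit 6 of 27 rose (10 adjusted over the list alone, set adjusted p = 7.27e-09, and 0.00459 with an estimated correlation). With an actin difference of 2.64 ± 1.15 (exact p = 0.127 against air), the actin fit called 226 genes that rose and 94 that fell, 309 shared with the spike-adjusted fit. In all, 591 genes rose and 1225 fell, and 683 rose and 458 fell in the spike-adjusted fit, with 707 shared in sign. The count of 1816 was 1158 without air replicate 3, 1128 without air replicate 2 and 936 without Af 24 h replicate 4. The spike-adjusted count of 1141 was 306 and 674 without Af 24 h replicates 3 and 2.

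The 24 h responses of SP-D-/- and C57BL/6 differed for 0 genes (limma, 564 at an unadjusted p under 0.05), and for 1 gene in the spike-adjusted fit, or 2, 3 and 3 without C57BL/6 Af 24 h replicates 1, 3 and 6 and 2 without SP-D-/- air replicate 2. In SP-D-/- acute-phase genes, higher in air, were lower in that test (median -0.77, camera adjusted p = 0.00209, and 0.737 with an estimated correlation), with 0 of 11 passing and 2 adjusted over the list alone. The count was 1 without C57BL/6 Af 24 h replicate 1, 2 without replicate 3 and 1 without SP-D-/- air replicate 2. The responses of BALB/c and C57BL/6 differed for 2 genes. Dbp, a clock output gene, was lower by -2.76 ± 0.50 and Sphk2, a sphingosine kinase, by -1.81 ± 0.33 (adjusted p = 0.00404 each), and both lost the call without C57BL/6 Af 24 h replicate 1 (adjusted p = 0.146), which left 0 genes. Both also lost it without the 5 arrays off their label, BALB/c Af 24 h replicates 4 and 5 among them (-2.19 and -1.45, adjusted p = 0.309 each, 0 genes), and with only the groups fitted (adjusted p = 0.782 each). In the spike-adjusted fit Dbp had -2.36 (adjusted p = 0.0496) and Sphk2 -1.49 (0.152), so most of the size stayed. Alveolar type 1 and club cell genes were lower in BALB/c as sets, with 0 of 9 and 0 of 14 passing (4 and 0 adjusted over the list alone, camera adjusted p = 6.92e-10 and 1.13e-05, and 0.256 and 0.312 with an estimated correlation). On the arrays labelled BALB/c Af 24 h replicates 4 and 5 type 1 genes differed by -1.60 and -3.27 from replicates 1 to 3, and on replicate 5 club genes by -2.31. In the spike-adjusted fit, without these arrays, the medians were -0.32 and -0.30, with 0 of 9 and 0 of 14 passing (0 and 0 adjusted over the list alone, camera adjusted p = 0.0255 and 0.0475, and 0.746 and 0.819 with an estimated correlation). Without C57BL/6 Af 24 h replicate 4 the count was 4.

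At 168 h after challenge with air, Mmp12, Saa3 and Retnla were raised in C57BL/6 lungs. Mmp12, macrophage elastase, rose by 4.42 ± 0.87 (adjusted p = 0.00156), from 4.13 ± 0.47 to 8.54 ± 1.77 (mean log2 ± SD, n = 6 and 4). The air level lay under 4.45, so the size is approximate. Saa3 rose by 4.14 ± 0.56 (adjusted p = 1.01e-06), Retnla by 2.53 ± 0.31 (adjusted p = 1.16e-07) and Slc26a4 by 3.07 ± 0.60 (adjusted p = 0.00156). A light chain variable segment of the Igkv14 family, part of antibodies, rose by 2.56 ± 0.41 (adjusted p = 6.91e-05). Genes of lipid-laden macrophages and lysosomes rose as a set, 5 of 16 up (8 up and 1 down adjusted over the list alone, camera adjusted p = 8.3e-07, and 0.226 with an estimated correlation). Cell cycle genes rose as a set, 2 of 27 up (9 adjusted over the list alone, adjusted p = 7.1e-08, and 0.12 with an estimated correlation). Endothelial genes fell as a set with 0 of 11 passing (6 fell adjusted over the list alone, adjusted p = 3.25e-05, and 0.339 with an estimated correlation). At 168 h the actin difference was 2.58 ± 0.43 (exact p = 0.00952 against air, and 0.0238 adjusted). The actin fit called 28 genes that rose and 7 that fell, all 35 shared with the spike-adjusted fit, with Mmp12 at 4.07 (adjusted p = 0.00243), Saa3 at 3.88 and Retnla at 2.40. In all, 164 genes rose and 40 fell, and 469 rose and 252 fell in the spike-adjusted fit, with all 204 shared in sign. The count of 204 was 454, 124, 53 and 47 without Af 168 h replicates 2, 3, 6 and 4, and 127 and 124 without air replicates 2 and 4. The spike-adjusted count of 721 was 1108, 390, 140 and 104 without Af 168 h replicates 2, 3, 6 and 4, and 410, 417 and 448 without air replicates 2, 4 and 6.

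In BALB/c lungs the largest rise at 168 h was that of Clca1, a secreted product of goblet cells, by 6.33 ± 0.87 (adjusted p = 9.88e-07), from 3.77 ± 0.56 to 10.11 ± 1.65 (n = 5 and 6). The air level lay under 4.45, so the size is approximate. Slc26a4 rose by 4.52 ± 0.57, Retnla by 4.26 ± 0.29 and Mmp12 by 4.03 ± 0.82. Jchain, the joining chain of secreted IgA and IgM, rose by 4.02 ± 0.79 (adjusted p = 0.00185). Chil3 and Chil4, chitinase-like proteins of type 2 inflammation, rose by 3.19 ± 0.39 and 3.31 ± 0.63. Goblet cell and mucus genes rose as a set, 4 of 15 up (5 adjusted over the list alone, camera adjusted p = 4.61e-09, and 0.0455 with an estimated correlation). Type 2 genes also rose as a set, 5 of 18 up (5 adjusted over the list alone, adjusted p = 3.03e-10, and 0.0455 with an estimated correlation). Clock genes fell as a set, 2 of 13 down (4 down and 1 up adjusted over the list alone), among them Dbp, by 1.95 ± 0.34 (set adjusted p = 0.0113, and 0.0455 with an estimated correlation). All 8 skeletal muscle genes fell, also adjusted over the list alone (set adjusted p = 5.56e-13, and 0.0455 with an estimated correlation), with Acta1, skeletal actin, down by 5.77 ± 1.21 from a mean of 9.86 ± 2.81 in air. The actin difference was 2.83 ± 0.37 at Af 168 h (exact p = 0.00866 against air, and 0.0238 adjusted), and the actin fit called 99 genes that rose and 70 that fell, 110 shared with the spike-adjusted fit. In all, 122 genes rose and 113 fell, and 167 rose and 114 fell in the spike-adjusted fit, with 156 shared in sign. The count of 235 was 84, 147, 94 and 152 without air replicates 3, 2, 4 and 6, and 379, 353, 145, 71 and 129 without Af 168 h replicates 2, 1, 4, 6 and 5. That of 281 in the spike-adjusted fit was 164, 177 and 141 without air replicates 3, 1 and 4 and 156 without Af 168 h replicate 6.

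In SP-D-/- lungs goblet cell genes rose as a set at 168 h, 3 of 15 up (10 adjusted over the list alone, camera adjusted p = 3.11e-08, and 0.133 with an estimated correlation). Clca1 rose by 3.52 ± 0.91 (adjusted p = 0.0285), from 7.54 to 11.07. Tmem256, a small membrane protein gene, rose by 1.83 ± 0.34 (adjusted p = 0.00125), from 7.25 ± 0.39 to 9.08 ± 0.62 (n = 5 and 5). The largest falls held liver and fat genes, whose levels differed between air arrays. Cyp2e1, a cytochrome of liver, fell by 3.44 ± 0.72 (adjusted p = 0.00591), Serpina1c, a protease inhibitor of liver, by 3.06 ± 0.82 (adjusted p = 0.0382), Adipoq, adiponectin of fat cells, by 2.67 ± 0.70 (adjusted p = 0.0307) and Alb, albumin, by 2.47 ± 0.65 (adjusted p = 0.0315). In air Alb was 6.99 ± 3.12 and Serpina1c 5.37 ± 4.10. Alb was 10.44 and 10.37 on air replicates 3 and 4 and ran from 4.58 to 4.95 on the other 3, and its call was lost without either of them or Af 168 h replicate 5 (adjusted p up to 0.267). The actin difference was 2.57 ± 0.67 at Af 168 h (exact p = 0.00794 against air, and 0.0238 adjusted), and the actin fit called 141 genes that rose and 51 that fell, 189 shared with the spike-adjusted fit. In all, 114 genes rose and 90 fell, and 342 rose and 172 fell in the spike-adjusted fit, with all 204 shared in sign. The count of 204 was 24, 99 and 79 without air replicates 3, 2 and 4, and 13 and 122 without Af 168 h replicates 5 and 6. In the spike-adjusted fit the count of 514 was 141 and 198 without air replicates 3 and 2 and 102 without Af 168 h replicate 5.

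The 168 h responses of SP-D-/- and C57BL/6 differed for 1 gene. Fbp1, fructose-bisphosphatase, was lower in SP-D-/- by -4.55 ± 0.89 (adjusted p = 0.036), and it lost the call in 14 of the 20 fits that left out 1 array, with adjusted p up to 0.362. The call was also lost with cyclic loess, the replicate block, only the groups fitted and in the actin fit (-3.82, adjusted p = 0.0537). Its mean was 3.12 ± 0.32 in C57BL/6 air and 3.32 ± 0.39 in SP-D-/- at Af 168 h, both under 4.45, so the size is approximate. It was 6.12 ± 1.79 in C57BL/6 at Af 168 h and 4.87 ± 1.72 in SP-D-/- air, with 6.54 and 6.95 on air replicates 3 and 4, the arrays high in Alb, and 3.43 to 3.79 on the others. The arrays were C57BL/6 air replicates 2, 4, 5 and 6, C57BL/6 Af 168 h replicates 3, 4 and 6, SP-D-/- air replicates 3 and 4, and SP-D-/- Af 168 h replicates 2 to 6. The count was 3 without C57BL/6 air replicate 1, 2 without C57BL/6 Af 168 h replicate 2 and 4 without SP-D-/- air replicate 2. In the test of the difference goblet genes were higher (median 0.65, camera adjusted p = 0.000384, and 0.576 with an estimated correlation) and lipid-laden macrophage genes lower in SP-D-/- (median -0.44, camera adjusted p = 0.0118, and 0.576 with an estimated correlation). No member of either list of 15 and 16 passed, also adjusted over the list alone.

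At 96 h after challenge with ozone, goblet cell genes were far above ozone alone in C57BL/6 and SP-D-/- lungs. Clca1 rose by 7.14 ± 0.87 in C57BL/6 (adjusted p = 1.36e-08), from 3.97 ± 0.80 to 11.11 ± 1.06 (mean log2 ± SD, n = 6 and 5), and by 7.51 ± 0.93 in SP-D-/- (adjusted p = 1.06e-07), from 3.72 ± 0.61 to 11.24 ± 0.94 (n = 4 and 6). Both ozone levels lay under 4.45, so these sizes are approximate. In SP-D-/- air Clca1 was at 7.54 ± 0.83, well above its ozone level. Slc26a4 rose by 4.26 ± 0.57 and 3.01 ± 0.60. Of 15 goblet cell and mucus genes 13 rose in C57BL/6 and 8 in SP-D-/- (14 and 10 adjusted over the list alone), and none fell. The sets rose (camera adjusted p = 3.69e-08 and 8.74e-09, and 0.138 and 0.085 with an estimated correlation), and in the spike-adjusted fit 8 members rose in each strain (9 and 12 adjusted over the list alone, adjusted p = 2.59e-07 and 1.86e-16, and 0.0933 and 0.00106 with an estimated correlation). In SP-D-/- Fcgbp, a mucus protein, rose by 4.08 ± 0.64, Agr2, a disulfide isomerase of mucin folding, by 3.38 ± 0.61 and Ccl8 by 4.24 ± 0.68. The median change of all genes in SP-D-/- was 0.11.

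Endothelial genes fell in C57BL/6 at 96 h. Of 11 members 9 fell and 0 rose (9 adjusted over the list alone, camera adjusted p = 5.91e-06, and 0.395 with an estimated correlation), and 8 fell in the spike-adjusted fit (8 adjusted over the list alone). Tek, the angiopoietin receptor, fell by 4.11 ± 0.59 (adjusted p = 3.88e-07) and Eng, endoglin, by 2.63 ± 0.38 (adjusted p = 4.5e-07). Thbd, thrombomodulin, fell by 4.17 ± 0.54 and Cd93, an endothelial lectin, by 4.60 ± 0.68. Of 9 alveolar type 1 genes 7 fell (8 adjusted over the list alone, set adjusted p = 0.000416, and 0.631 with an estimated correlation), among them Clic5, by 1.83 ± 0.31, and Hopx, by 2.10 ± 0.49. Of 15 fibroblast and matrix genes 10 fell and 2 rose (10 and 2 adjusted over the list alone, set adjusted p = 0.000353, and 0.395 with an estimated correlation), among them Dcn, a matrix proteoglycan, by 2.52 ± 0.38. These genes also passed in the spike-adjusted fit. Ssty1 and Ssty2, multicopy genes of spermatids, rose by 3.74 and 3.90, but had -0.13 and -0.04 in the spike-adjusted fit, where neither passed.

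In all, 2590 genes rose and 2890 fell at 96 h in C57BL/6, and 1454 rose and 862 fell in the spike-adjusted fit, with 1615 shared in sign. In C57BL/6 the actin difference was 2.87 ± 0.29 at 96 h and 1.72 ± 0.19 with ozone alone (exact p = 0.00433, and 0.0238 adjusted), and 917 rose and 486 fell in the actin fit, with 1341 shared in sign with the spike-adjusted fit. In the actin fit 6 endothelial genes fell (7 adjusted over the list alone, camera adjusted p = 2.08e-06, and 0.111 with an estimated correlation), with Tek at -2.82 and Eng at -1.84, and 6 goblet genes rose (9 adjusted over the list alone, adjusted p = 1.6e-07, and 0.111 with an estimated correlation), with Clca1 at 6.80. In SP-D-/- it was 2.70 ± 0.50 and 2.75 ± 0.39 (exact p = 0.819), and 286 rose and 69 fell in the actin fit. In SP-D-/- 355 rose and 34 fell, and 211 rose and 40 fell in the spike-adjusted fit, with 216 shared in sign. The SP-D-/- count of 389 was 1186, 202 and 41 without ozone replicates 3, 2 and 5 and 189 without the array labelled Af 96 h replicate 1. The spike-adjusted count was 1507 without ozone replicate 5 in C57BL/6, and 50 without ozone replicate 5 and 81 without Af 96 h replicate 4 in SP-D-/-. The spike level in SP-D-/- was 9.41 ± 0.61 at Af 96 h and 10.38 ± 1.29 with ozone alone.

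The 96 h responses of SP-D-/- and C57BL/6 differed for 2529 genes that were higher and 1598 that were lower in SP-D-/-, but for 21 and 28 in the spike-adjusted fit, with 39 shared in sign. Tnc, the matrix protein tenascin C, was higher by 4.78 ± 0.73 (adjusted p = 4.97e-05, with 1 of its 2 probe sets in this direction) and Ndnf, a neuron-derived neurotrophic factor gene, by 5.60 ± 0.94 (adjusted p = 0.000297). They were the 2 of 21 named genes that passed in the spike-adjusted fit, with 3.05 ± 0.62 (adjusted p = 0.0136) and 2.89 ± 0.68 (adjusted p = 0.0358). In the actin fit 0 genes passed (limma, 1400 at an unadjusted p under 0.05), with Tnc at 3.05 and Ndnf at 3.10 (adjusted p = 0.0549 each). Endothelial genes had a median of 1.32, with 6 of 11 up (7 adjusted over the list alone), and were not called as a set (camera adjusted p = 0.0575, and 0.888 with an estimated correlation). Goblet cell genes were not called either (adjusted p = 0.432). Fibroblast and matrix genes were higher as a set, 10 of 15 up and 1 down (10 and 1 adjusted over the list alone, camera adjusted p = 0.000778, and 0.888 with an estimated correlation). The median of all genes was 0.20. The count of 4127 was 2596 and 1553 without SP-D-/- ozone replicates 2 and 5, and in the spike-adjusted fit the count of 49 was 0 and 28 without C57BL/6 ozone replicates 5 and 3, and 11, 156 and 138 without C57BL/6 Af 96 h replicates 2, 4 and 6. It was 25, 82 and 31 without SP-D-/- ozone replicates 2, 4 and 5, and 32, 15 and 15 without SP-D-/- Af 96 h replicates 2, 4 and 5.

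In BALB/c lungs 8 genes rose and 0 fell at 96 h, and 22 rose and 1 fell in the spike-adjusted fit. With an actin difference of 3.08 ± 0.66 against 2.16 ± 0.19 with ozone alone (exact p = 0.143), the actin fit called 10. Ccl8 rose by 4.62 ± 0.87 (adjusted p = 0.00456), Slc26a4 by 4.39 ± 0.76 and Chil3 by 3.09 ± 0.53 (adjusted p = 0.00135 each), the last from 8.91 ± 0.33 to 11.99 ± 0.21 (n = 2 and 6). Type 2 genes rose as a set, 2 of 18 up (4 adjusted over the list alone, camera adjusted p = 1.88e-11), as did cell cycle genes, 0 of 27 up (7 adjusted over the list alone, adjusted p = 1.7e-10), each with 0.0127 with an estimated correlation. Clca1, chosen after its values were seen, had 4.88 ± 1.17 and did not pass (adjusted p = 0.0833). Without ozone replicate 1 or 3 the count was 0 (limma), and in the spike-adjusted fit it was 7 and 6.

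**Figure D4:**
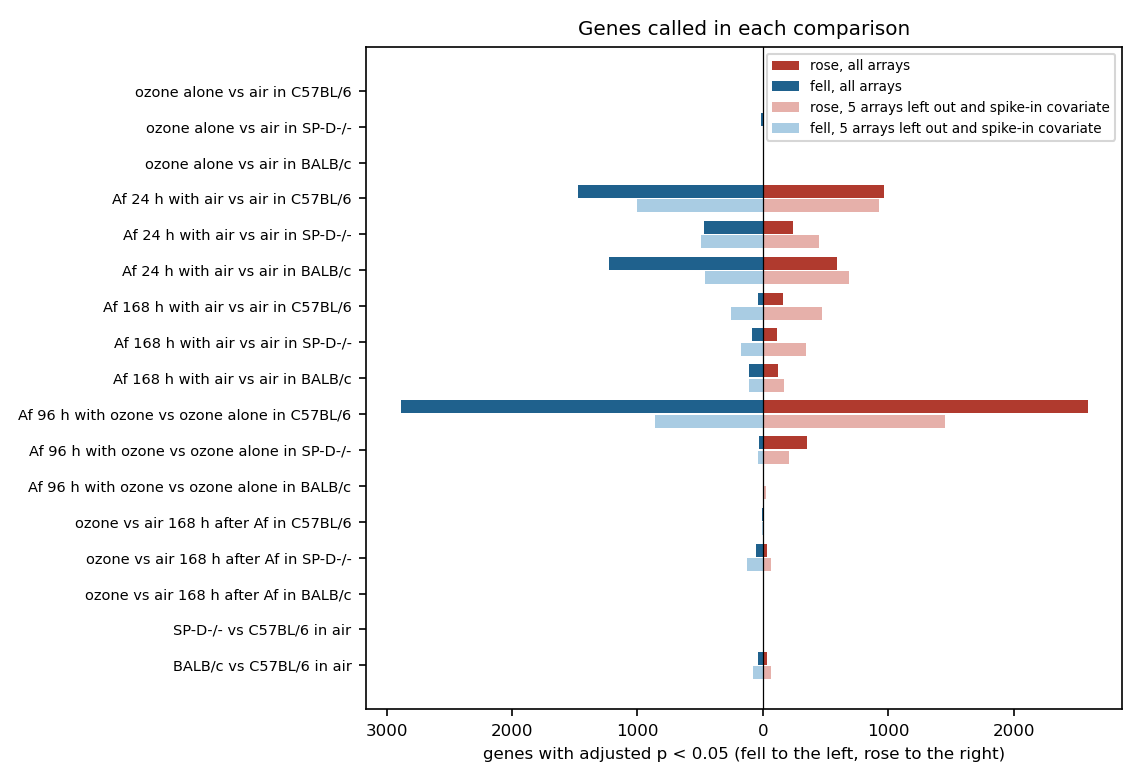
Number of genes called (adjusted p under 0.05) that rose (right) or fell (left), for all 89 arrays and the spike-adjusted fit of 84. Differences between responses are not shown. In C57BL/6 at Af 96 h with ozone the counts were 5480 and 2316.

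At 168 h after challenge, ozone was compared with air. In C57BL/6, the Igkv14 segment fell with ozone by 2.99 ± 0.41 (adjusted p = 4.74e-06), from 7.34 ± 0.96 to 4.35 ± 0.38 (n = 4 and 6), and was the 1 of 9 named genes that kept its call whichever array was left out. With only the 2 groups fitted it did not pass (-2.99, adjusted p = 0.177), and 0 of the 9 kept the call in all alternatives chosen beforehand. Fibroblast and matrix genes fell as a set with 0 of 15 passing (7 adjusted over the list alone, camera adjusted p = 1.18e-05, and 0.203 with an estimated correlation). In all, 1 gene rose and 8 fell, and all 9 were shared with the spike-adjusted fit. The count of 9 was 39, 479, 59, 2, 5 and 1 without ozone replicates 2, 1, 3, 4, 6 and 5, and 5, 1 and 3 without air replicates 3, 6 and 4. The spike-adjusted count of 14 was 49, 95, 25, 2, 6 and 2 without ozone replicates 2, 1, 3, 4, 6 and 5, and 9, 22, 1 and 4 without air replicates 3, 2, 6 and 4.

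In SP-D-/- lungs Ucp1, the uncoupling protein of brown fat, rose with ozone at 168 h by 2.64 ± 0.51 (adjusted p = 0.00436), from 4.11 ± 0.32 to 6.75 ± 1.84 (n = 5 and 4). The level with air lay under 4.45, so the size is approximate. Of 8 skeletal muscle genes 2 rose (8 adjusted over the list alone, camera adjusted p = 2e-10, and 0.151 with an estimated correlation), and their mean level was 4.70 ± 0.19 with air and ran from 6.88 to 9.67 with ozone. In all, 33 genes rose and 58 fell, and all 91 were shared with the spike-adjusted fit. The count of 91 was 948, 16, 715 and 6 without ozone replicates 3, 1, 4 and 6, and 25, 42 and 24 without air replicates 2, 5 and 4. In the spike-adjusted fit the count of 192 was 888, 48, 749 and 20 without ozone replicates 3, 1, 4 and 6, and 126, 117 and 121 without air replicates 2, 3 and 5. The 2 strains differed in this response for 6 genes. The Igkv14 segment was higher in SP-D-/- by 3.04 ± 0.60 (adjusted p = 0.00908), but not without C57BL/6 Af 168 h air replicate 4 or 6 (adjusted p up to 0.128), and 0 of 5 named genes kept the call in all alternatives chosen beforehand. The count of 6 was 0 and 3 without C57BL/6 Af 168 h air replicates 6 and 4, 13 without C57BL/6 Af 168 h ozone replicate 1, and 11, 16 and 12 without SP-D-/- Af 168 h ozone replicates 1, 4 and 6.

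In BALB/c lungs 2 genes rose and 1 fell with ozone at 168 h. Sphk2 fell by 1.32 ± 0.23 (adjusted p = 0.00429), Gpx2, a glutathione peroxidase, rose by 1.71 ± 0.36 and Rpsa, a ribosomal protein gene, by 0.73 ± 0.15 (adjusted p = 0.0462 each). Without the array labelled ozone replicate 6, which had the markers of SP-D-/-, none passed (Sphk2 at -1.15, adjusted p = 0.166, so most of its size stayed), and the spike-adjusted fit called 0 genes (limma, 941 at an unadjusted p under 0.05). The count of 3 was 1, 7, 20, 1 and 1 without air replicates 3, 2, 1, 4 and 5, and 1 and 0 without ozone replicates 5 and 6.

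The ozone response 168 h after challenge was also set against the ozone response without allergen. In C57BL/6, Saa3 went from 4.98 to 8.06 with ozone alone and from 9.12 to 7.96 after challenge, a difference of -4.23 ± 0.75 (adjusted p = 0.0019, and 0.0606 without Af 168 h air replicate 6, which left a count of 1). The Igkv14 segment went from 4.78 to 5.14 and from 7.34 to 4.35, a difference of -3.36 ± 0.56 (adjusted p = 0.000774). These 2 genes were all that passed, and neither kept the call in all alternatives chosen beforehand. Acute-phase genes were lower as a set, 1 of 11 (6 adjusted over the list alone, camera adjusted p = 1.18e-06, and 0.123 with an estimated correlation). In BALB/c 1 gene passed, Retnla, with -3.57 ± 0.51 (adjusted p = 1.66e-05). Its level was 12.47 ± 0.26 at Af 168 h with air and 12.44 ± 0.20 with ozone, against 8.21 ± 0.63 in air and 11.75 ± 0.09 with ozone alone. The highest value of 13.5 leaves little room for a further rise, so the difference does not show a smaller response. In SP-D-/- 0 genes passed (limma, 935 at an unadjusted p under 0.05), and 1, 2, 8 and 3 did without ozone replicate 5 or Af 168 h ozone replicates 3, 4 and 6.

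In air, SP-D-/- lungs differed from C57BL/6 lungs in 10 genes, 9 higher and 1 lower. Besides Sftpd, Saa3 was higher by 3.31 ± 0.52 (adjusted p = 7.67e-05), at 8.29 ± 0.94 against 4.98 ± 0.79 (n = 5 and 6). Ctr9, a subunit of the Paf1 transcription complex, was higher by 2.72 ± 0.27 (adjusted p = 9.8e-12), Loxl2, a lysyl oxidase of the matrix, by 2.32 ± 0.41 and Retnla by 1.65 ± 0.29 (adjusted p = 0.000944 each). The fibrinogen genes Fgg and Fga were among the 9, higher by 2.03 ± 0.40 (adjusted p = 0.00604) and 2.03 ± 0.45 (adjusted p = 0.0299), at 6.07 ± 1.96 and 6.32 ± 2.20 in SP-D-/- air. On air replicates 3 and 4, the arrays high in Alb, Fgg was 7.59 and 8.53 and Fga 8.30 and 9.10, and without either array neither gene passed. Fga also lost the call without any of C57BL/6 air replicates 1, 2, 4, 5 and 6. Acute-phase genes were higher as a set, 1 of 11 (1 adjusted over the list alone, camera adjusted p = 1.15e-11, and 0.00468 with an estimated correlation). This set was not tested without the 2 arrays high in Alb, so how far they carry it stays open. B cell and NK cell genes were lower as sets, with medians of -0.67 and -0.34 and no member of 7 and of 9 passing, also adjusted over the list alone (adjusted p = 2.46e-07 and 4.65e-07, and 0.0149 and 0.00468 with an estimated correlation). All 10 genes were shared with the spike-adjusted fit, which called 14, or 40, 39, 31 and 8 without SP-D-/- air replicates 2, 6, 5 and 4 and 9 without C57BL/6 air replicate 2. The count of 10 was 5, 33, 26, 25 and 6 without SP-D-/- air replicates 3, 2, 6, 5 and 4.

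BALB/c lungs differed from C57BL/6 lungs in air in 77 genes, 36 higher and 41 lower, all shared with the spike-adjusted fit, which called 147. H2-Ea, a class II antigen-presenting gene that C57BL/6 mice do not express, was higher by 4.70 ± 0.48 (adjusted p = 2.99e-11), and Dbp by 2.07 ± 0.34 (adjusted p = 3.5e-05). Klra8, an NK cell receptor gene, was lower by -3.29 ± 0.56 (adjusted p = 8.51e-05), Chil3 by -1.85 ± 0.39 (adjusted p = 0.00386) and Retnla by -1.51 ± 0.29 (adjusted p = 0.00104). B cell and NK cell genes were lower as sets, 0 of 7 and 0 of 9 passing (2 and 3 adjusted over the list alone, camera adjusted p = 3.71e-08 and 3.14e-05, and 0.015 each with an estimated correlation). Of 73 genes that differed between BALB/c and C57BL/6 at least 2-fold, 61 (83.6%, exact 95% interval 73.1 to 91.2) were nearer the C57BL/6 level in SP-D-/- lungs at Af 168 h with air. The labels do not state the background of SP-D-/-.

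**Figure D5:**
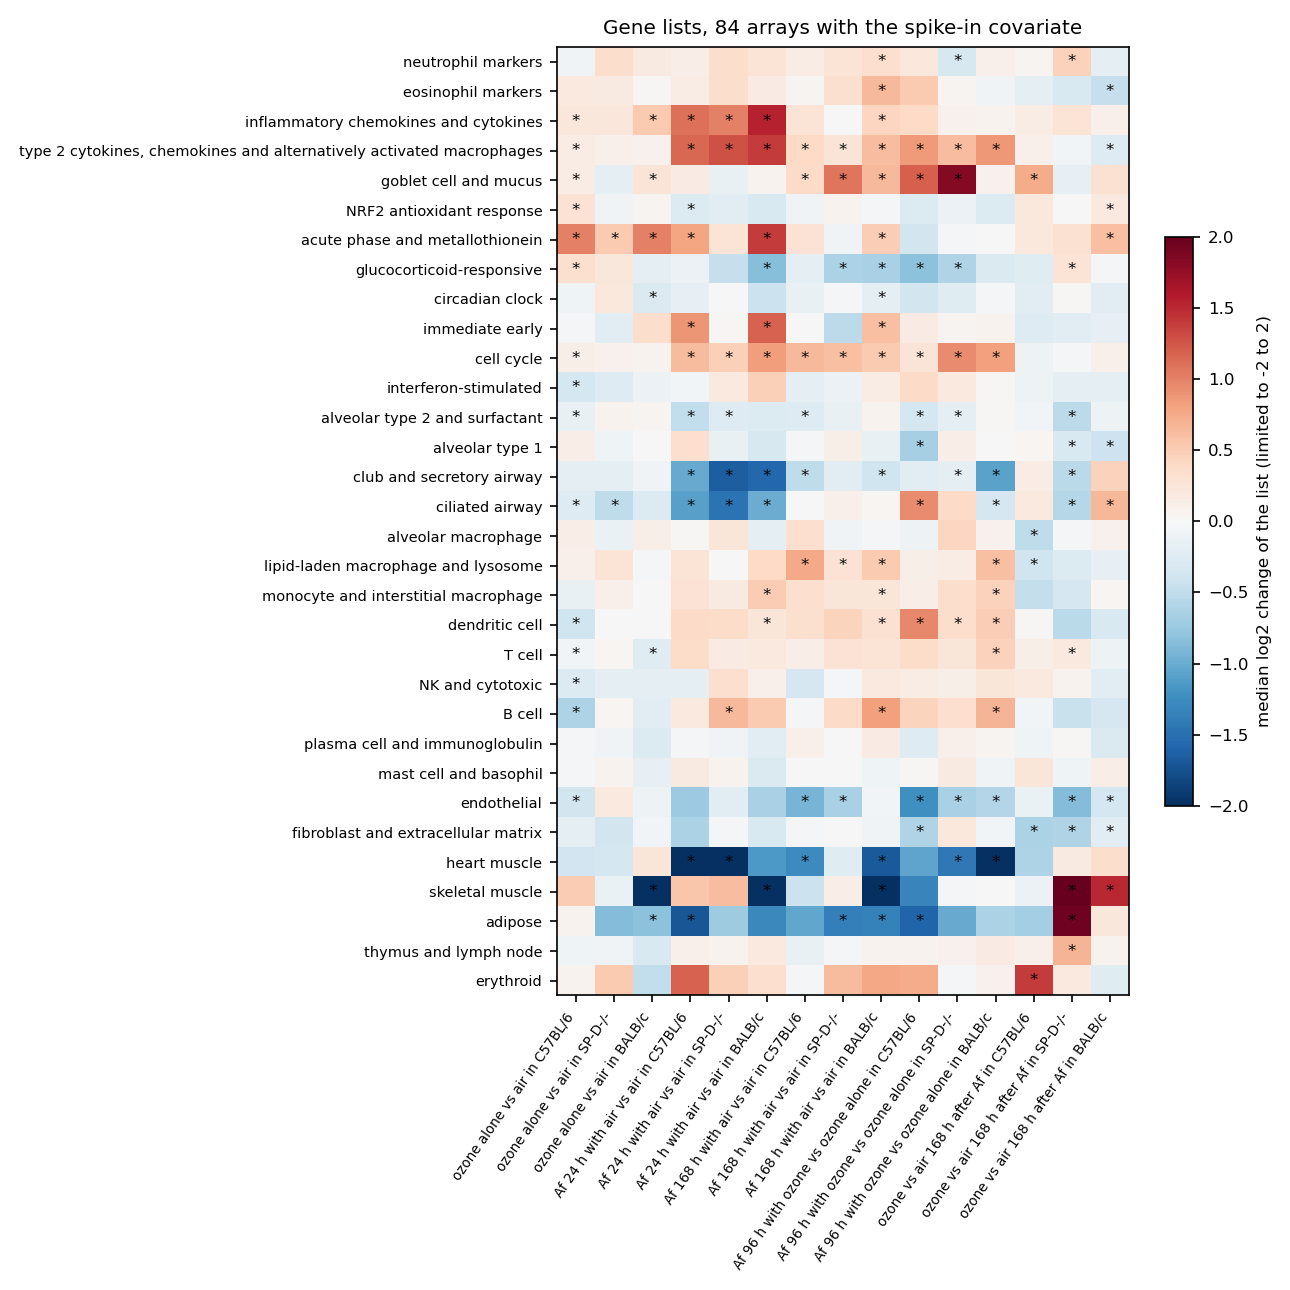
Median log2 change of each gene list (vertical axis) in each comparison (horizontal axis) in the spike-adjusted fit, as colour, with a star where the camera adjusted p was under 0.05. Club and secretory genes at Af 24 h and goblet cell genes at Af 96 h were among the lists with a star.

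With an estimated correlation 28 of the 200 camera calls over 27 comparisons held. Besides those given above with an adjusted p under 0.05, they were heart muscle in BALB/c at 96 h (median -3.08, 0 of 8, 7 adjusted over the list alone, 0.0127), skeletal muscle higher in BALB/c than C57BL/6 in air (median 2.50, 0 of 8, 8 adjusted over the list alone, 0.015), skeletal muscle in 2 tests of a difference that hold BALB/c air (0.00423 and 0.00813), and adipose genes in the ozone response of SP-D-/- after challenge against that without (0.0422). Neutrophil, mast cell and basophil markers were called in none of the 27 comparisons.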

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

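The tests of a wrong label, of low array quality, of a swap, of cells of another type in 1 array, of how many genes, goblet genes and genes of the strain difference pass again with the spike level, of the air genes on other arrays, and of splits that part or keep the pairs were chosen after the result was seen, as were the spike-adjusted fit and the fit with the actin difference. Single arrays lay far from the others of their group in 7 of 51 tests, where chance gives about 1 in 20 groups. Differences between groups in a response, by a test of the difference, make up the rest.

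Sftpd was 5.59 on the array labelled BALB/c Af 168 h with ozone replicate 6 and 10.94 on the array labelled SP-D-/- Af 96 h with ozone replicate 1, each far from its group. The strain index was -0.5 on the first of these and 0.63 on the array labelled C57BL/6 Af 96 h with ozone replicate 1. A wrong label may explain the first and the third, since on both (2 of 2) the strain genes outside the index lay on the side of 1 other strain, 11 of 16 (median position 0.64, with -1 the label and 1 the other strain) and 13 of 14 (0.95), but for the SP-D-/- label only 2 such genes exist (median position 0.711, with Ctr9 at 6.78, within C57BL/6, and Loxl2 at 4.42, within SP-D-/-), so it stays open there. A swap within the exposure is argued against for the C57BL/6 label, since 0 arrays of the resembled strain carried the markers of the labelled strain. For the others it stays open, as replicate numbers are missing in the resembled group. Low array quality is argued against, since each marker off its label lay at least 6.11 residual SD from the line on the spike level, and biological explanations were not tested.

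The arrays labelled BALB/c Af 24 h replicates 4 and 5 had Sftpd at 8.79 and 7.68. RNA mixed in from SP-D-/- lungs is argued against for both. For replicate 5 the share needed was 0.938 by Sftpd, 0.954 by genes higher in BALB/c and 0.007 by genes lower in BALB/c, a gap of 0.947, and for replicate 4 the gap was 0.908. Cells of another type may account for replicate 5, where cell cycle genes were 1.64 above replicates 1 to 3, alveolar type 1 genes differed by -3.27 and fibroblast genes by 0.33. In 4 of 5 epithelial and endothelial lists the mean was at least 1 lower. Low array quality was not tested for either and stays open (spike level 11.72 on replicate 4, group mean 10.04).

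The 96 h response differed between SP-D-/- and C57BL/6 for 4127 genes, for 49 in the spike-adjusted fit and for 0 with the actin difference added (limma, 1400 at an unadjusted p under 0.05). Array signal and RNA quality may account for this difference, since 0.9% of its genes (39) passed again with the same sign with the spike level in the fit, where their median went from 1.75 (median SE 0.55) to 0.61 (0.46). Across the 5480 called genes of C57BL/6 alone, the log2 change followed the slope on the spike level in other groups. There r was 0.839 (rho = 0.845, genes not being independent replicates). Signal and RNA quality may account for much of that response. Whether for all is open: 1615 (29.5%) passed again, 983 in the actin fit. For the 2316 genes of the spike-adjusted fit 3' bias of the RNA may account for part. Their change correlated with the slope on the actin difference with r = 0.622 (rho = 0.572). Such bias is argued against as the whole cause, since 57.9% (1341) passed again in the actin fit. For the 13 called goblet genes signal is argued against as the whole cause, since 7 (53.8%) passed again with the spike level. But the slope gave 32.9% of their median change of 1.83, so its share stays open, as does the exposure. In SP-D-/- part of the goblet list rose with the spike level lower by -0.97.

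The spike level was 10.86 on C57BL/6 ozone replicate 5, far above the others of its group. The strain index was -0.1 on C57BL/6 Af 24 h replicate 1 and -1.09 on SP-D-/- ozone replicate 3, each far from its group but on the side of its label. The Af 168 h response differed between SP-D-/- and C57BL/6 for 1 gene and the ozone response at Af 168 h for 6. The Af 24 h response differed between BALB/c and C57BL/6 for 2 genes. The ozone response after challenge differed from that without challenge for 2 genes in C57BL/6 and 1 in BALB/c.

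Other splits of the same arrays into groups of the same sizes were fitted, with at most 100 per comparison and the real one included. A result as large came from 1 split, the real one, for ozone in C57BL/6 (4 genes, highest other 1), Af 24 h in SP-D-/- (709, highest other 302) and BALB/c (1816, highest other 491), and Af 168 h in C57BL/6 (204, highest other 26), SP-D-/- (204, highest other 8) and BALB/c (235, highest other 66). The same held for Af 96 h in C57BL/6 (5480, highest other 2207), BALB/c against C57BL/6 in air (77, highest other 34), and the difference between SP-D-/- and C57BL/6 at Af 96 h (4127, highest other 9). It came from 2 splits for Af 24 h in C57BL/6 (2437, highest other 3107) and Af 96 h in SP-D-/- (389, highest other 574). In these chance can be excluded at a share under 0.05. For the ozone response after against without challenge in C57BL/6 it came from 3 (2, highest other 6). With the replicate pairs kept it was 1 (highest other 1). For the difference at Af 168 h between SP-D-/- and C57BL/6 the real split alone gave 1 gene (highest other 0). With only the groups fitted both counts were 0, as was the latter with cyclic loess and with the replicate block. So these calls depend on the method.

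Chance cannot be excluded for ozone in SP-D-/- (11 splits, 15 genes, highest other 45), the count in SP-D-/- against C57BL/6 in air (8 splits, 10 genes, highest other 32), and ozone at Af 168 h in SP-D-/- (9 splits, 91 genes, highest other 2939) and BALB/c (7 splits, 3 genes, highest other 2350). Nor can it for the difference between SP-D-/- and C57BL/6 in the last response (24 splits, 6 genes, highest other 960, or 14 splits and 2301 when the pairs were kept), and between BALB/c and C57BL/6 at Af 24 h (17 splits, 2 genes, highest other 611). For 4 of 9 air genes besides Sftpd chance is excluded by the other 5 exposures, where they differed less. Ctr9 and Loxl2 (adjusted p = 4.5e-05 each) kept the sign in 5, Mfsd2a (0.00054) and Saa3 (0.00785) in 4. With 0 genes called by limma the splits decide nothing, since all 100 must be as large. This holds for the differences between SP-D-/- and C57BL/6 with ozone (highest other 7, 1157 genes at an unadjusted p under 0.05) and at Af 24 h (highest other 6, 564), and for the ozone response after against without challenge in SP-D-/- (highest other 3199, 935). For ozone at Af 168 h in C57BL/6 the replicate numbers may pair the arrays. The 16 splits that part the same 4 pairs are too few for a share under 0.05 (2 as large, 9 genes, highest other 18). They differ from the real split by exchanging the arrays within pairs. Splits that ignored the pairs gave as many in 28 of 100 (highest other 5437). Splits that called several times the real count point to a structure of the samples other than the groups.

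In the spike-adjusted fit the real split alone gave as many genes in all 8 allergen comparisons that were split. They were Af 24 h in C57BL/6 (1927, highest other 292), SP-D-/- (937, highest other 99) and BALB/c (1141, highest other 87, of 56 splits), and Af 168 h in C57BL/6 (721, highest other 221), SP-D-/- (514, highest other 47) and BALB/c (281, highest other 101). At Af 96 h they were C57BL/6 (2316, highest other 516) and SP-D-/- (251, highest other 35). Comparisons with BALB/c ozone were not split, since that group holds 2 arrays.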

How the results depend on the processing

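The spike level and the actin difference as covariates, the fit without the 5 arrays whose markers were off their label, and their combinations were chosen after seeing the data, and the other settings before. Where a value below differs from the reported one the cause was not tested. Of the 27 counts, 27 stayed within 1.5 times the reported count with no filter, 24 with cyclic loess, 23 with the mean of probe sets, 23 with the replicate block, 11 with only the groups of the comparison, 16 with the spike level, 18 without the 5 arrays, 12 with both, 14 with both and the replicate block and 13 with both and the actin difference. Of the 200 list calls 28 held with an estimated correlation, 80 with fry, 189 with the replicate block, 184 with cyclic loess, 175 in the spike-adjusted fit and 41 in that fit with an estimated correlation, and 0 reversed. The nearness to C57BL/6 of SP-D-/- strain genes was 81.3% with cyclic loess and 84.4% with genes of at least 1.5-fold. Genes near the lower limit of 4.45 carry little information.

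With cyclic loess the count was 3 for ozone at Af 168 h in C57BL/6, 1 in BALB/c, and 0 for the difference between SP-D-/- and C57BL/6 at Af 168 h. With the mean of probe sets it was 4 for Af 96 h in BALB/c, 4 for ozone at Af 168 h in C57BL/6, 0 in BALB/c, and 1 for the difference between BALB/c and C57BL/6 at Af 24 h.

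With only the groups of the comparison the count was 51 for ozone in C57BL/6, 1252 for Af 24 h in SP-D-/- and 752 in BALB/c, 2056, 326 and 894 for Af 168 h in C57BL/6, SP-D-/- and BALB/c, and 30 for Af 96 h in BALB/c. It was 0, 4 and 0 for ozone at Af 168 h in C57BL/6, SP-D-/- and BALB/c, 28 for SP-D-/- and 437 for BALB/c against C57BL/6 in air, 0 for the differences at Af 168 h between SP-D-/- and C57BL/6 and at Af 24 h between BALB/c and C57BL/6, and 0 and 2 for the ozone response after against without challenge in C57BL/6 and SP-D-/-.

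With the replicate block the count was 45 for ozone in SP-D-/-, 1 for ozone at Af 168 h in BALB/c, and 1 and 0 for the differences between SP-D-/- and C57BL/6 with ozone and at Af 168 h. Ozone at Af 168 h in C57BL/6, the comparison whose replicate numbers may pair the arrays, had 8 with the block. Of its named genes Klhl24 (adjusted p = 0.0506) and Slc7a1 (adjusted p = 0.0562) lost the call, and no other call of a named gene or list changed.

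With the spike level as a covariate the count was 4 for ozone in SP-D-/-, 1574 for Af 24 h in C57BL/6, 456 and 347 for Af 168 h in C57BL/6 and SP-D-/-, 2105 and 16 for Af 96 h in C57BL/6 and BALB/c, 5 and 5 for ozone at Af 168 h in C57BL/6 and BALB/c, 116 for BALB/c against C57BL/6 in air, and 1 and 5 for the differences between SP-D-/- and C57BL/6 at Af 24 h and Af 96 h. Without the 5 arrays it was 680 for Af 24 h in BALB/c, 338, 327 and 386 for Af 168 h in C57BL/6, SP-D-/- and BALB/c, 15 for Af 96 h in BALB/c, 16, 310 and 0 for ozone at Af 168 h in C57BL/6, SP-D-/- and BALB/c, and 0 for the difference between BALB/c and C57BL/6 at Af 24 h.

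With both it was 1 for ozone in SP-D-/-, 1141 for Af 24 h in BALB/c, 721 and 514 for Af 168 h in C57BL/6 and SP-D-/-, 2316, 251 and 23 for Af 96 h in C57BL/6, SP-D-/- and BALB/c, 14, 192 and 0 for ozone at Af 168 h in that order, 147 for BALB/c against C57BL/6 in air, 1, 49 and 10 for the differences between SP-D-/- and C57BL/6 at Af 24 h, Af 96 h and with ozone at Af 168 h, and 1 for that between BALB/c and C57BL/6 at Af 24 h. The correlation of ozone responses of C57BL/6 and SP-D-/- was 0.208. With both and the replicate block the counts were 7 for ozone in C57BL/6, 1085 for Af 24 h in SP-D-/-, 785 and 625 for Af 168 h in C57BL/6 and SP-D-/-, 2311, 234 and 23 for Af 96 h, 0 for ozone at Af 168 h in BALB/c, 157 for BALB/c against C57BL/6 in air, 1, 118 and 11 for the same differences between SP-D-/- and C57BL/6, and 1 for that between BALB/c and C57BL/6.

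With both and the actin difference the count was 0 for ozone in SP-D-/- (limma, 1128 at an unadjusted p under 0.05), 512 and 320 for Af 24 h in C57BL/6 and BALB/c, 35 for Af 168 h and 1403 for Af 96 h in C57BL/6, 229 and 0 for ozone at Af 168 h in SP-D-/- and BALB/c, and 146 for BALB/c against C57BL/6 in air. The differences between SP-D-/- and C57BL/6 had 1, 0, 0 and 10 at Af 24 h, Af 168 h, Af 96 h and with ozone at Af 168 h, that between BALB/c and C57BL/6 at Af 24 h had 0, and the ozone response after against without challenge in SP-D-/- had 8.

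Of the named genes 16 values changed sign. With the mean of probe sets Car3 had 0.227 at Af 24 h in C57BL/6, Lpcat1 0.274 at Af 96 h in C57BL/6 and Pdxdc1 0.191 for BALB/c against C57BL/6 in air. At Af 96 h in C57BL/6 Ssty2 had -0.037 with both, 0 with both and the replicate block and -0.028 with both and the actin difference, and Ssty1 -0.043 with the spike level, -0.134 with both, -0.091 with both and the replicate block and -0.09 with both and the actin difference. In the difference between SP-D-/- and C57BL/6 at Af 96 h Ssty2 had 0.044 with both and 0.033 with both and the actin difference, and Prl2c2 0.26 with the spike level, 0.347 with both, 0.256 with both and the replicate block and 0.002 with both and the actin difference.

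Leaving out each array gave counts of 3 to 6, 1 to 454 and 1 to 2 for ozone in C57BL/6, SP-D-/- and BALB/c, 944 to 4076, 435 to 946 and 936 to 2381 for Af 24 h, 47 to 454, 13 to 282 and 71 to 379 for Af 168 h, 4414 to 6267, 41 to 1186 and 0 to 9 for Af 96 h, and 1 to 479, 6 to 948 and 0 to 20 for ozone at Af 168 h, in the same order of strains. It gave 5 to 33 for SP-D-/- and 54 to 78 for BALB/c against C57BL/6 in air. The differences between SP-D-/- and C57BL/6 gave 0 to 10 with ozone, 0 to 2 at Af 24 h, 0 to 4 at Af 168 h, 1553 to 5328 at Af 96 h and 0 to 16 with ozone at Af 168 h. Those between BALB/c and C57BL/6 gave 0 to 0 with ozone (limma, 131 genes at an unadjusted p under 0.05 with all arrays) and 0 to 4 at Af 24 h. The ozone response after against without challenge gave 1 to 3, 0 to 8 and 1 to 1. Sftpd in SP-D-/- against C57BL/6 ran from -3.92 to -3.70 in air, -4.98 to -4.16 with ozone, -3.75 to -3.33 at Af 24 h, -3.53 to -2.71 at Af 96 h, and -3.64 to -3.19 with air and -4.54 to -3.77 with ozone at Af 168 h. The correlations of ozone responses ran from -0.343 to 0.224 for C57BL/6 and SP-D-/-, -0.077 to 0.141 for C57BL/6 and BALB/c and 0.086 to 0.41 for SP-D-/- and BALB/c. Where 1 ozone array of BALB/c was left, it was assumed to vary like the arrays of the other groups.

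Counts of the spike-adjusted fit also moved by over 1.5 times without 1 array, in these comparisons and in those where the report gives it. Ozone in BALB/c had 5 without ozone replicate 1 (2 with all), and ozone at Af 168 h in BALB/c 1 without air replicate 6 (0 with all, by limma, and 941 at an unadjusted p under 0.05). The difference at Af 168 h between SP-D-/- and C57BL/6, 1 with all, was 2 without C57BL/6 Af 168 h replicate 2 or SP-D-/- Af 168 h replicate 2, and 0 without any of C57BL/6 air replicates 1, 3 and 6, C57BL/6 Af 168 h replicates 3, 4 and 6, SP-D-/- air replicates 3 and 4, and SP-D-/- Af 168 h replicates 4 and 6. That with ozone at Af 168 h, 10 with all, was 6 without C57BL/6 Af 168 h air replicate 4 or 6, 53 and 33 without C57BL/6 Af 168 h ozone replicates 1 and 5, 19 without SP-D-/- Af 168 h air replicate 5, and 128, 79 and 22 without SP-D-/- Af 168 h ozone replicates 3, 4 and 6. That between BALB/c and C57BL/6 at Af 24 h, 1 with all, was 2 and 3 without C57BL/6 Af 24 h replicates 3 and 4, and 0 without C57BL/6 Af 24 h replicate 1, any C57BL/6 air array, any of BALB/c air replicates 1, 3, 4 and 6 or any of BALB/c Af 24 h replicates 1 to 3. The ozone response after against without challenge, 2 with all in C57BL/6, was 0 without Af 168 h air replicate 6. In SP-D-/- it was 0 with all (limma), and 8, 10 and 11 without air replicates 2, 6 and 5, 13 and 3 without ozone replicates 3 and 5, 21 without Af 168 h air replicate 6, and 188, 13, 168 and 9 without Af 168 h ozone replicates 3, 1, 4 and 6.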

Other observations

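All tests in this part were planned before their result was seen, but the genes of single arrays were chosen afterwards. Skeletal muscle genes differed widely between arrays of a group. Their mean over 8 genes was 8.01 ± 2.42 (log2, mean ± SD, n = 5) in BALB/c air, where it ran from 4.81 to 10.67, and 4.34 ± 0.19 (n = 6) in BALB/c at Af 168 h with air. In C57BL/6 air it was 5.34 ± 1.85 (n = 6), with 1 array at 9.11. On the array labelled BALB/c Af 24 h replicate 5, Hmga2, a chromatin protein of growing cells, was 5.17 above replicates 1 to 3, Aspn, a matrix protein, 4.62 above and Pdgfc, a growth factor, 4.28 above.

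Muscle tissue carried along with some lungs may account for the skeletal muscle genes. The prediction was that these genes would rise and fall together within groups, and their median pairwise correlation was 0.897. Array signal and RNA quality is argued against, since the correlation of their mean with the spike level within groups was -0.079. The falls of these genes with ozone and at Af 168 h in BALB/c, and their rise with ozone at Af 168 h in SP-D-/-, are therefore open to a difference in dissection, which the labels do not record.

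Genes that differ between SP-D-/- and C57BL/6 in air could be alleles carried along with the disrupted Sftpd locus. Of 9 called genes other than Sftpd with a known chromosome, 1 (Loxl2) lay on that of Sftpd, against 513 of 15029 tested genes (3.41%). The one-sided Fisher exact p was 0.268, so with 9 genes the test cannot tell such alleles from other differences between the strains.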
